A study of Mus musculus with 21 samples.

How the data were processed

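RNA sequencing libraries of C3H/10T1/2 mouse mesenchymal cells were grouped by the histone H2B they carried: wild type (WT) or E71K, E71Q, E76K, E76Q, E113K or E113Q, with 3 libraries in each of the 7 groups. The deposited files give TPM (transcript abundance normalized to length and to a fixed total) for 24091 genes in the 21 libraries, and the authors added the mean TPM of the 3 libraries of each group, which was not used further. Per the labels, RNA was taken with an RNeasy kit and libraries were made with NEBNext Ultra II, and whether RNA was selected by poly(A) or the libraries were stranded is not stated. The submitters' notes name Salmon, featureCounts 1.4.4 and DESeq with genome build mm10, without saying which of them made the TPM values. Each library's TPM summed to between 999897 and 999931. Counts were not used here, and TPM keeps no read total, so the depth is unknown and neither counting intervals nor limits for values of 0 can be given. An H2B transgene cannot be told from the endogenous genes in these values. Replicate numbers were not used as pairs.

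Genes with a mean of at least 1 TPM over the 21 libraries were tested (12192 genes), and 3934 genes were at 0 in every library. Values were used as deposited, as log2(TPM + 1). A linear model of the 7 groups was fitted to all 21 libraries with limma 3.58.1 in R 4.3.3, with moderated variances and an intensity trend (14 residual and 3.19 prior degrees of freedom). There were 15 comparisons between 2 groups (6 of a mutant with WT, and 9 between mutants that share a residue or a substituted amino acid), 3 interactions of the lysine minus glutamine difference between residues, and an F test of any difference among the groups. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p below 0.05 are called risen or fallen. Errors are SD over 3 libraries for TPM and SE of the model for log2 fold changes.

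Before the data were examined 37 lists of genes were fixed, and the 33 with at least 5 tested members were compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over the 198 tests of 33 lists in 6 mutants. Camera with a correlation estimated from the data and camera on ranks were alternatives. The genes to be named were also fixed by rule: for each mutant against WT the 8 called genes with the largest rise and the 8 with the largest fall, between mutants 4 of each, up to 4 called members of a list, and Runx2, Pparg, Sox9, Acta2, Cdkn1a, Mki67 and Col1a1 in every mutant. Genes named for the size of their change had a mean of at least 5 TPM and every library of a group on the same side of the other group, which was not asked of list members or these 7. The value of a list in a library is the median over its members. Gene positions are those of GRCm38 (mm10), matched by Entrez Gene identifier for 24045 symbols. The similarity of mutants was measured as the correlation and covariance of their fold changes against WT, beside 50 draws of unchanged groups set against shared controls. In 20 simulations of unchanged groups at most 4 genes were called over the 6 comparisons.

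The axis of differences within groups is the first principal component of the libraries after each group's mean was removed, made without the group whose libraries are placed on it. A library was set apart where its group spanned more than 10 on the axis, as the library farthest from its mates. The alternatives tried were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 TPM, a median-ratio rescaling on 8056 genes above 5 TPM in every library, quantile normalization, moderation without the trend and robust moderation, replicate number as a block, an absolute log2 fold change of at least 1, fits of only the 6 libraries compared, and each library left out in turn. Leaving out Mir6236, leaving out the libraries set apart and the list tests between mutants were added after the data were seen. The procedure was tested on 21 simulated libraries, drawn with independent normal noise around each gene's mean, with 200 of 12192 genes changed in E71K. Against WT, 41.8% of those changed 1.5-fold, 79.1% of those changed 2-fold and 93.9% of those changed 4-fold were recovered, and 5 unchanged genes were called. These data had no axis within groups, no unequal spread between groups and no correlation between genes, so recovery in the real data can differ.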

Results

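RNA was sequenced from C3H/10T1/2 cells, a mouse embryo line of mesenchymal progenitor cells, that carried either wild-type histone H2B (WT) or H2B in which 1 glutamate had been replaced. Glutamate E71, E76 or E113 was changed to lysine (E71K, E76K, E113K) or to glutamine (E71Q, E76Q, E113Q). Lysine reverses the charge of the residue and glutamine removes it. Glutamate E113 lies in the acidic patch, the negatively charged surface of the nucleosome that many chromatin proteins bind, and glutamate E76 faces histone H4. There were 7 groups of 3 libraries, 21 libraries in all, each given as TPM (length-normalized transcript abundance with a fixed sum in each library) for 24091 genes. TPM keeps no read total, so the sequencing depth of each library is unknown. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels name no independent cell lines for a genotype. A difference between lines therefore cannot be told apart from an effect of the substitution.

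Libraries of a group resembled each other closely. The correlation of log2(TPM + 1) across genes was 0.935 to 0.979 within groups and 0.863 to 0.946 between groups, and 20 of the 21 libraries had their best match in their own group. The exception was E71K replicate 3, whose best match was an E71Q library. The share of TPM taken by a single locus annotated as a microRNA, Mir6236, ran from 2.19% in E113K replicate 3 to 30.6% in E71K replicate 2 and 21.2% in E71Q replicate 1. Which RNA gave the reads at this locus cannot be told from these values. Along the main axis of differences between mates, which held 22.7% of the variance within groups, the 3 libraries spanned 41.6 in E71K, 26.2 in E71Q, 28.7 in E76K and 30.7 in E113Q, but 2.4 in WT, 0.6 in E76Q and 3.2 in E113K. The library farthest from its mates was replicate 3 in E71K, E76K and E113Q and replicate 1 in E71Q. WT lay at the lower end of the axis (-30.6 to -28.2), and E76Q (18.5 to 19.1) and E113K (17.1 to 20.3) at the upper end.

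**Figure D1:**
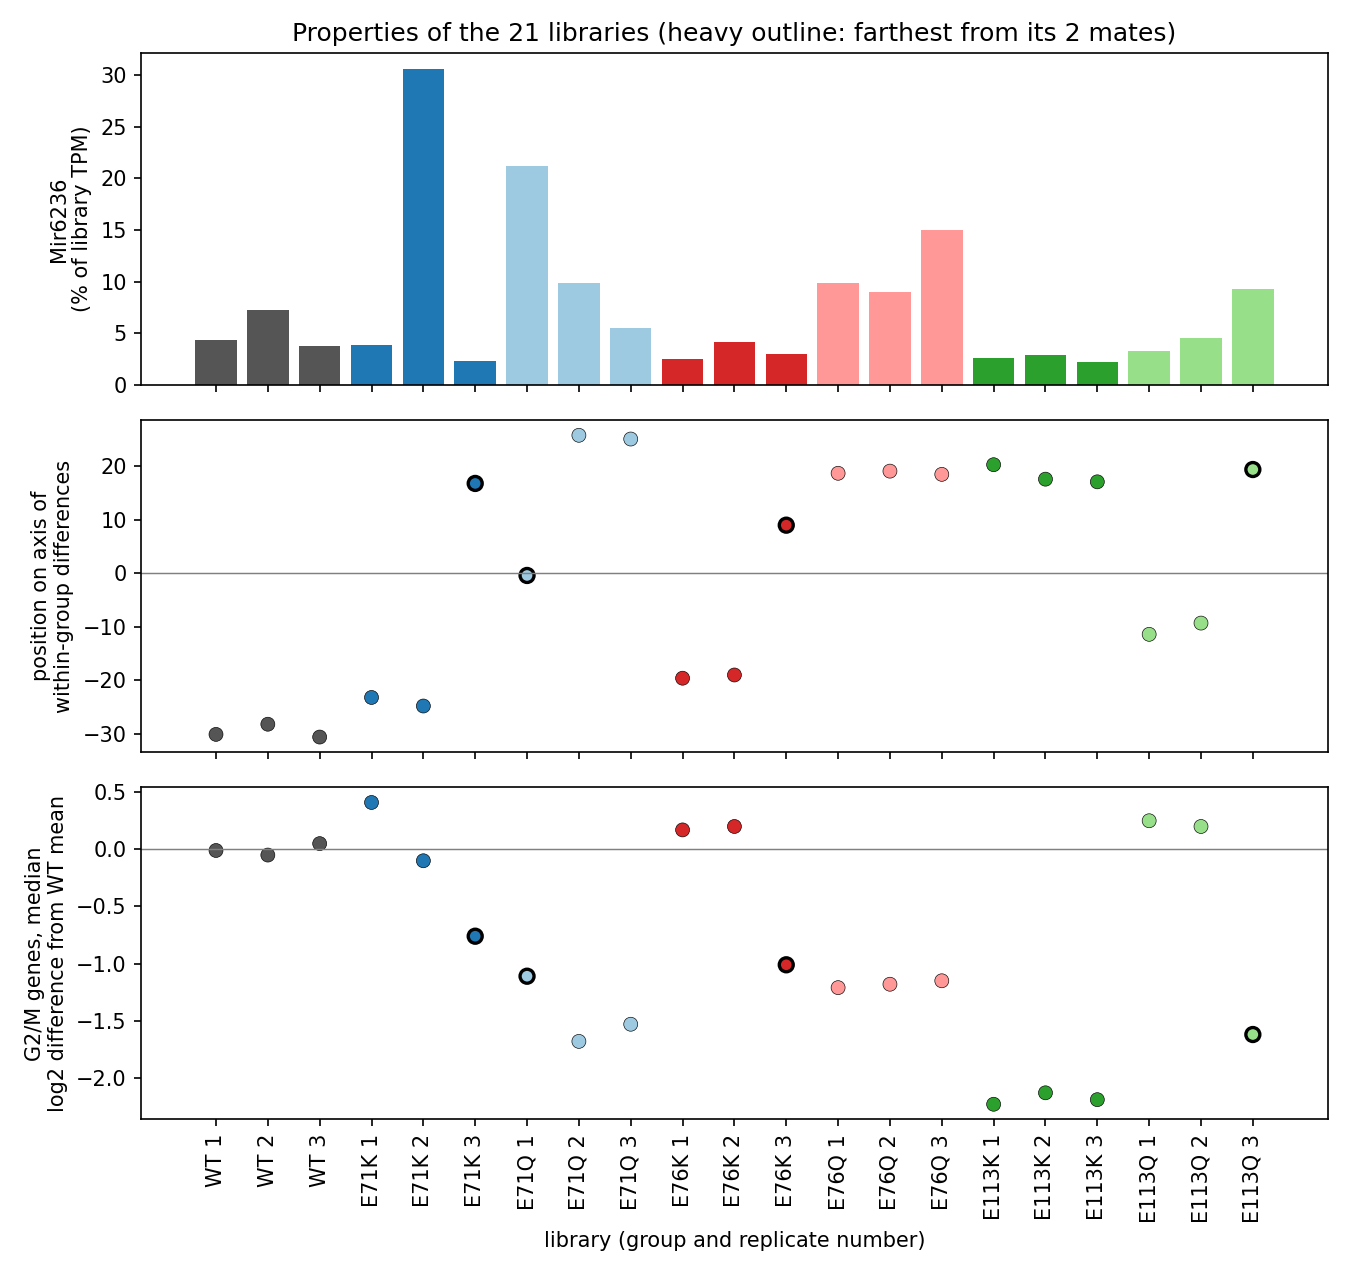
Share of TPM taken by Mir6236 (percent), position on the axis of differences within groups (arbitrary units) and median log2 difference from WT of the G2/M genes, with 1 point for each of the 21 libraries; a heavy outline marks the library farthest from its mates. The E71K, E71Q, E76K and E113Q libraries spread along the axis by 26.2 to 41.6, and the 3 E113K libraries have the lowest G2/M values, -2.23 to -2.13.

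Each of the 6 mutants differed from WT in many transcripts. Of 12192 genes tested with limma, 6215 passed an adjusted p of 0.05 in E113K (51%), 5403 in E76Q (44.3%), 5388 in E71Q (44.2%), 4044 in E76K (33.2%), 3734 in E113Q (30.6%) and 3250 in E71K (26.7%). Those that also changed at least 2-fold numbered 2200, 1894, 1908, 1261, 1215 and 1201 in the same order. The fit used a single spread for each gene over all groups, so counts of groups with more or less spread are not strictly comparable. The E71K count depended on the setting: it was 1442 in a fit of the 6 libraries alone, 5135 after a median-ratio rescaling, 5238 with Mir6236 left out and 4939 without the 4 libraries that lay apart. The share of its genes that rose was 46.9%, but 32.1% without E71K replicate 3 and 69.8% without E71K replicate 2. Any difference among the 7 groups was called for 9404 genes by the limma F test. The median log2 fold change of all tested genes was 0.16 in E76K and 0.13 in E113K, against 0.01 for either after the rescaling, so rises in these 2 mutants are to be read against that shift. Fold changes are differences of mean log2(TPM + 1), which understate the change of genes near 0.

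**Figure D2:**
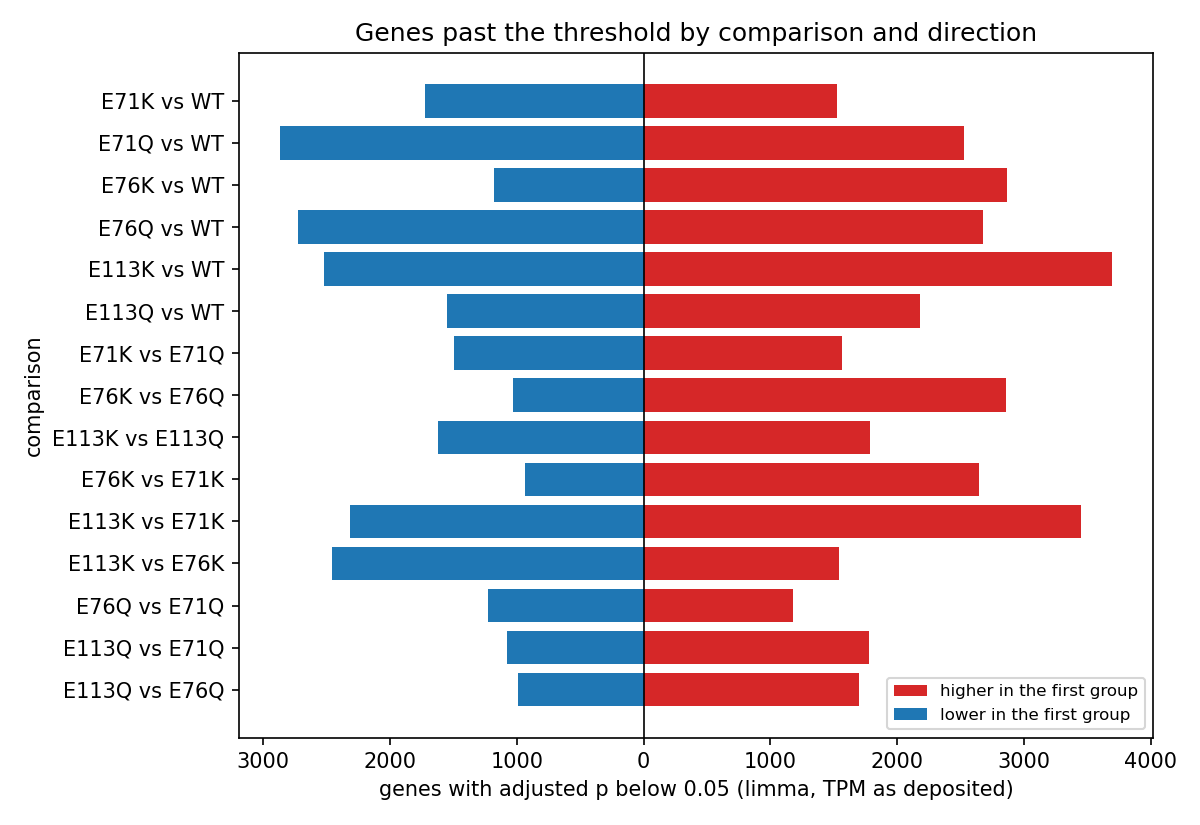
Number of genes that rose (positive bars) or fell (negative bars) at an adjusted p below 0.05 in each of the 15 comparisons between 2 groups, out of 12192 genes tested. The counts are largest for E113K against WT (3692 rose, 2523 fell; 59.4% rose, and 50.6% after the median-ratio rescaling).

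A set of 445 genes rose and 360 fell in all 6 mutants, and 439 and 353 of these did so after the rescaling too. Without the 4 libraries that lay apart the numbers were 590 and 419. Sprr2b, which encodes a small proline-rich protein of the cornified envelope of epithelia (Entrez Gene 20756; chromosome 3, 92316705 to 92318085), stood at 512 ± 60.2 TPM in WT (SD, n = 3) and at 2.94 ± 1.22 TPM or less in every mutant group. Myl9, a myosin regulatory light chain, fell from 107 ± 2.51 TPM in WT by a mean of 6.13 on the log2 scale over the 6 mutants, and the noncoding RNA Lncenc1 fell from 76.9 ± 1.56 TPM by a mean of 6.05. Among the genes that rose in all 6, the Wnt agonist Rspo2 had a mean log2 fold change of 4.67, the glycine receptor subunit Glrb 4.18, the pentraxin Ptx3 4.17 and the fibrillar collagen Col11a1 3.61. The imprinted growth factor receptor adaptor Grb10 had 3.48 and the adhesion molecule Ncam1 2.85. Hist1h3a fell from 266 ± 7.74 TPM by a mean of 7.19, but this gene and Hist1h3h have near-identical histone copies among which reads can be divided, so their values are uncertain. The same holds for Sprr2b beside the other Sprr2 genes, Prl2c2, Hba-a2 and Bglap2. Because all 6 mutants were set against the same 3 WT libraries, part of what they share may come from those libraries.

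**Figure D3:**
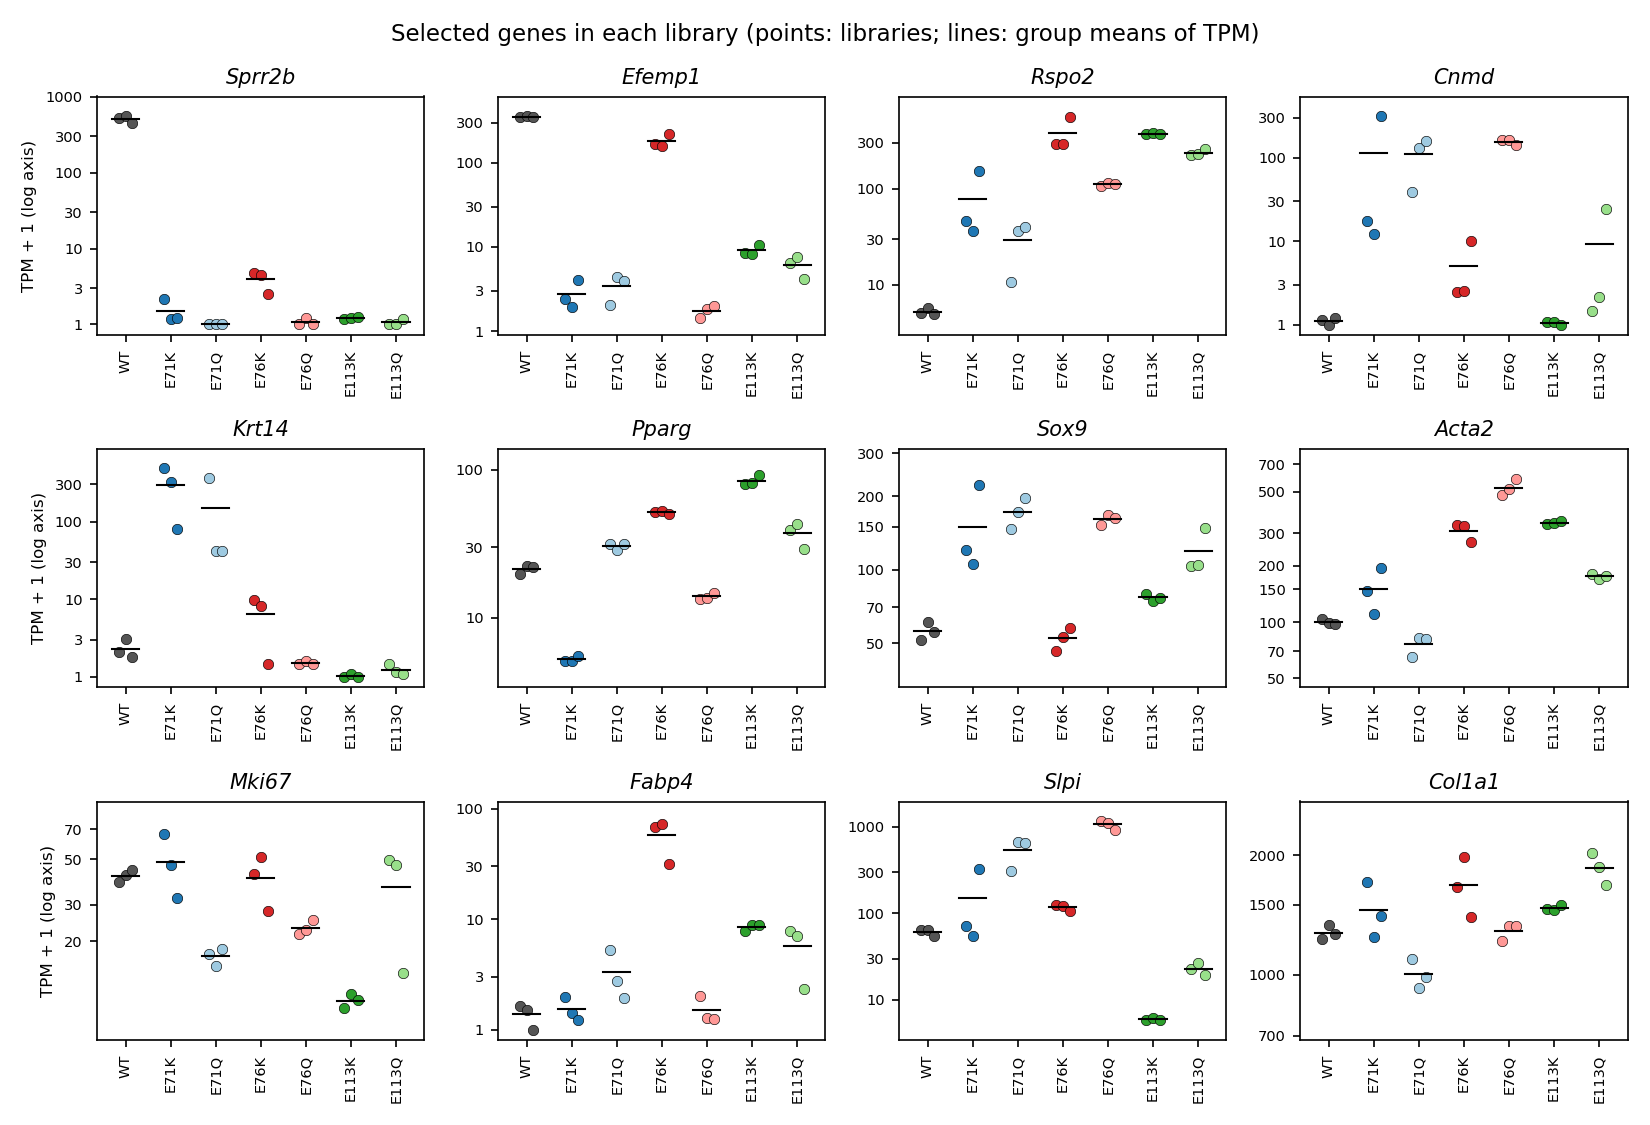
TPM + 1 (log axis) of 12 genes in the 21 libraries, with 1 point for each library and a bar at each group's mean. Sprr2b is below 5 TPM in every mutant group against 512 TPM in WT, and Rspo2 is higher in every mutant than its 4.27 TPM in WT.

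In E71K, where lysine replaces glutamate E71, Krt14 had the largest rise of the named genes. Krt14, a keratin of basal epithelial cells (Entrez Gene 16664; chromosome 11, 100203162 to 100207510), was at 294 ± 203 TPM in E71K against 1.31 ± 0.678 TPM in WT (SD, n = 3). Its log2 fold change was 6.68 ± 0.77 (SE; limma adjusted p = 2.85e-06), with 483.3, 319.6 and 79.07 TPM in the 3 E71K libraries. Cnmd, the cartilage protein chondromodulin, rose by 5.17 ± 1.05 (adjusted p = 0.00111), but its E71K libraries held 16.17, 11.09 and 309.6 TPM and the rise was 3.70 without replicate 3. Fmod, the collagen-binding proteoglycan fibromodulin, rose to 36.9 ± 18.9 TPM from 0.346 ± 0.103 TPM, and Cyp26b1, a retinoic acid-degrading enzyme, to 143 ± 40 TPM from 5.44 ± 0.181 TPM. Wfdc12, Celf2 and Glrb rose by 4.53, 4.39 and 4.36 on the log2 scale. Plac8 fell from 199 ± 2.30 to 0.164 ± 0.149 TPM and Efemp1, the matrix protein fibulin-3, from 348 ± 7.26 to 1.77 ± 1.09 TPM. Arl6ip1, which shapes the endoplasmic reticulum, fell from 169 ± 1.07 to 0.913 ± 0.021 TPM, and Prl2c2, a proliferin, from 225 ± 25.1 to 1.28 ± 1.45 TPM. Among the 7 genes followed in every group, Sox9, a transcription factor of cartilage, rose from 55.2 ± 4.71 to 148 ± 63.1 TPM and Acta2, smooth muscle actin, from 99.2 ± 3.83 to 149.6 ± 41.6 TPM. Pparg, the regulator of fat cell differentiation, fell from 20.4 ± 1.37 to 4.26 ± 0.258 TPM. The others did not pass the test: Runx2 (12.3 ± 7.45 against 13.6 ± 2.81 TPM), Cdkn1a (238 ± 41.1 against 271 ± 1.48 TPM), Mki67 (47.7 ± 17.2 against 40.7 ± 2.84 TPM) and Col1a1 (1450.4 ± 236 against 1275 ± 50.6 TPM).

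Of the 33 gene lists tested, 7 passed camera in E71K. Chondrocyte genes rose (8 of 13 tested members, 8 adjusted over the list alone), as did BMP target genes (12 rose and 1 fell of 14, 12 and 1 adjusted over the list alone), and NF-kB and inflammatory genes fell (13 of 22, 13 adjusted over the list alone). The adjusted p was 7.07e-06, 1.06e-06 and 1.44e-06 with the preset correlation, and each list had adjusted p = 0.987 with an estimated correlation. The median of the chondrocyte list stood at 2.42, 2.06 and 3.51 log2 units over WT in the 3 libraries. Fgfr3 and Cytl1 rose by 3.35 and 3.83, the homeobox gene Dlx5 and the inhibitor of DNA binding Id4 by 3.41 and 2.23, while Grem1, a secreted BMP antagonist on the BMP list, fell by 5.65. The chemokine genes Ccl2 and Ccl7 fell by 4.21 and 3.67. Ribosomal protein genes (27 fell and 1 rose of 78, 33 and 1 adjusted over the list alone) and amino acid response and ATF4 target genes (9 fell of 26, 11 adjusted over the list alone) were lower (adjusted p = 1.13e-06 and 0.0025), with adjusted p = 0.987 with an estimated correlation for either. TGF-beta target genes (9 rose and 2 fell of 23, 10 and 2 adjusted over the list alone) and Hox genes (5 rose of 12, 6 rose and 1 fell adjusted over the list alone) were higher (adjusted p = 0.0267 and 0.0293), again with adjusted p = 0.987 with an estimated correlation. After the rescaling these 2 lists had an adjusted p of 0.0647 and 0.0553, and the ATF4 list had 0.312 without the libraries that lay apart. Without those libraries camera also passed cholesterol synthesis genes as lower (18 fell and 1 rose of 24, adjusted p = 3.4e-05). It passed G2/M genes (7 rose and 2 fell of 38, 0.0129) and replication-dependent histone genes (12 rose and 6 fell of 54, 0.0206) as higher. As deposited these lists had 0.987, 0.988 and 0.988 with an estimated correlation.

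In E71Q, where glutamine replaces the same residue, an osteocalcin gene and several cartilage transcripts were among the highest risers. Bglap2, an osteocalcin gene (Entrez Gene 12097; chromosome 3, 88377736 to 88378701), was at 663 ± 491 TPM against 0.77 ± 0.289 TPM (SD, n = 3). Its log2 fold change was 8 ± 1.29 (SE; limma adjusted p = 9.06e-05), and replicate 1 held far less than the 889.7 and 999.7 TPM of its mates. Cytl1, a secreted protein of cartilage, was listed at 0 in all WT libraries and at 112 ± 29.5 TPM in E71Q. Cnmd rose by 6.38 ± 1.05, Eln, elastin, by 6.17 ± 0.93 and Ucma, a secreted protein of growth plate cartilage, by 5.78 ± 1.35, and in each the library farthest from its mates, replicate 1, held the lowest value (37.18, 8.457 and 8.425 TPM). Smoc2, a secreted calcium-binding protein, fell from 388 ± 12.1 to 0.519 ± 0.1 TPM. Efemp1, Plac8, Arl6ip1 and Prl2c2 fell as in E71K, to 2.42 ± 1.21, 0.442 ± 0.306, 1.06 ± 0.419 and 0.952 ± 1.15 TPM. Of the 7 genes followed in every group 3 rose, Sox9 (171 ± 24.8 TPM), Pparg (29.7 ± 1.6 TPM) and the cell cycle inhibitor Cdkn1a (336 ± 17.5 TPM). Acta2 (74.9 ± 9.58 TPM), the proliferation marker Mki67 (15.9 ± 1.6 TPM) and Col1a1 (1002 ± 86.6 TPM) fell. Runx2 was at 8.04 ± 3.06 TPM (adjusted p = 0.0694).

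Cell cycle lists fell in E71Q. Of 38 G2/M genes 34 fell (37 adjusted over the list alone) and of 36 G1/S genes 32 fell (32 adjusted over the list alone), with adjusted p = 8e-07 and 1.55e-08 with the preset correlation and adjusted p = 0.987 with an estimated correlation. Bub1 and Top2a fell by 2.09 and 1.78, and Uhrf1 by 2.08. Ribosomal protein genes (66 fell of 78, 68 adjusted over the list alone) and amino acid response and ATF4 target genes (22 fell of 26, 22 adjusted over the list alone) were lower as well (adjusted p = 9.49e-13 and 1.96e-07, and adjusted p = 0.987 with an estimated correlation for either). Slc7a5, an amino acid transporter, and Cth fell by 2.52 and 2.43. Chondrocyte genes (10 rose of 13, 10 adjusted over the list alone) and BMP target genes (11 rose and 1 fell of 14, 11 and 1 adjusted over the list alone) were higher, with adjusted p = 1.55e-06 and 0.000135 and adjusted p = 0.987 with an estimated correlation. Hapln1 and Matn4, components of cartilage matrix, rose by 4.77 and 4.59. NF-kB and inflammatory genes (15 fell and 2 rose of 22, 15 and 2 adjusted over the list alone) and smooth muscle and contractile genes (9 fell of 15, 9 adjusted over the list alone) were lower. So were histone chaperones and H2B ubiquitin writers (18 fell and 1 rose of 25, 18 and 1 adjusted over the list alone) and developmental transcription factors (17 fell and 4 rose of 37, 18 and 4 adjusted over the list alone). In this order their adjusted p was 0.000361, 0.00128, 0.000361 and 0.00875, and each had adjusted p = 0.987 with an estimated correlation. The contractile gene Actg2 fell by 5.28, the histone chaperone subunit Chaf1a by 1.56 and the transcription factor Tbx1 by 4.57. Replication-independent histone variants (6 fell of 11, 8 fell and 1 rose adjusted over the list alone) were lower, and collagen and matrix genes (20 rose and 7 fell of 35, 22 and 9 adjusted over the list alone) and cholesterol synthesis genes (6 rose and 1 fell of 24, 5 and 0 adjusted over the list alone) were higher. These 3 lists had adjusted p = 0.0134, 0.0154 and 0.0357, and adjusted p = 0.987 with an estimated correlation. The cholesterol list had 0.0601 after the rescaling (10 rose) and 20 risen genes without the libraries that lay apart, and it stood at -0.30 in replicate 1 against 0.71 and 0.74 in its mates.

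In E76K lysine replaces glutamate E76, and the largest rise of the named genes was that of Rspo2. Rspo2 (Entrez Gene 239405; chromosome 15, 43020788 to 43171594) was at 380.4 ± 150.3 TPM against 4.27 ± 0.394 TPM in WT (SD, n = 3). Its log2 fold change was 6.11 ± 0.46 (SE; limma adjusted p = 1.27e-08). Nov, the matricellular protein CCN3 on the same chromosome, was at 1682 ± 717 against 34.2 ± 0.843 TPM, and Fabp4, the fatty acid binding protein of fat cells, at 56.3 ± 22.6 against 0.382 ± 0.336 TPM. Gabra3, a subunit of the GABA receptor, Brinp3 and Abi3bp rose by 5.34, 5.22 and 5.04 on the log2 scale, and Abi3bp was at 157.1 TPM in replicate 3 against 45.61 and 46.93 TPM in its mates. Sprr2b, Myl9, Lncenc1 and Crmp1 fell by 7.07, 6.39, 5.62 and 5.37, and Ccdc184 fell from 48.9 ± 2.99 to 0.312 ± 0.0806 TPM. Efemp1 fell too, by 0.96. Acta2 (308 ± 35.7 TPM), Pparg (50.9 ± 1.45 TPM) and Col1a1 (1677 ± 291 TPM) rose, though Col1a1 had an adjusted p of 0.233 after the rescaling. Runx2 (16.9 ± 5.82 TPM), Sox9 (51.2 ± 5.70 TPM), Cdkn1a (264 ± 6.30 TPM) and Mki67 (39.5 ± 11.7 TPM) did not pass the test. Of the called genes 70.8% rose, against 53.1% after the rescaling.

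In E76K, BMP target genes (10 rose and 1 fell of 14, 10 and 1 adjusted over the list alone) and matrix metalloproteinases and protease inhibitors (12 rose of 19, 13 adjusted over the list alone) were higher, with adjusted p = 0.00118 and 0.00956 and adjusted p = 0.987 with an estimated correlation. Dlx5 and Id3 rose by 3.14 and 1.88, and the protease gene Mmp3 by 2.55. Ribosomal protein genes (31 fell of 78, 34 adjusted over the list alone), G1/S genes (8 fell of 36, 3 adjusted over the list alone) and histone chaperones and H2B ubiquitin writers (7 fell and 1 rose of 25, 7 and 1 adjusted over the list alone) were lower (adjusted p = 2.58e-14, 4.46e-06 and 0.029, and adjusted p = 0.987 with an estimated correlation for each). After the rescaling 68 ribosomal genes, 16 G1/S genes and 15 of the chaperone list fell, and 15 G1/S genes did without the libraries that lay apart. The replication helicase genes Mcm2 and Mcm4 fell by 0.95 and 0.83. For 4 further lists the median-ratio rescaling ended the call. These were replication-dependent histone genes (8 fell and 2 rose of 54, 4 and 1 adjusted over the list alone, adjusted p = 0.00342 and 0.12 after the rescaling) and immediate early genes (6 fell and 2 rose of 26, 5 and 2 adjusted over the list alone, 0.0209 and 0.085). The others were cell adhesion receptors (12 fell and 9 rose of 31, 12 and 10 adjusted over the list alone, 0.0243 and 0.163) and G2/M genes (2 fell of 38, 0 adjusted over the list alone, 0.0144 and 0.127). Each had adjusted p = 0.987 with an estimated correlation. The G2/M list stood at -1.01 in replicate 3 and at 0.17 and 0.20 in its mates, and had an adjusted p of 0.893 without the libraries that lay apart.

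In E76Q, where glutamine replaces glutamate E76, Cnmd had the largest rise of the named genes, and the 3 libraries lay within 0.6 of each other on the axis. Cnmd (Entrez Gene 16840; chromosome 14, 79637682 to 79662194) was at 153 ± 11.9 against 0.115 ± 0.105 TPM in WT (SD, n = 3). Its log2 fold change was 7.11 ± 1.05 (SE; limma adjusted p = 3.8e-05). Fmod rose to 115 ± 7.15 TPM, the cartilage proteoglycan Chadl to 49.4 ± 3.42 from 0.124 ± 0.0314 TPM, Ptx3 to 258 ± 10.3 from 3.75 ± 0.358 TPM and Il1rn, the interleukin 1 receptor antagonist, to 123 ± 2.64 from 2.27 ± 0.391 TPM. Bglap2 rose by 5.85. Efemp1 fell to 0.742 ± 0.268 TPM, Prl2c2 to 0.126 ± 0.109 TPM and Msln, the surface protein mesothelin, from 104 ± 5.39 to 0.0496 ± 0.0859 TPM. Acta2 rose 5.29-fold to 525 ± 51.9 TPM and Sox9 to 159.8 ± 7.92 TPM, while Pparg fell to 13.0 ± 0.590 TPM. Runx2 (17.6 ± 4.33 TPM), Cdkn1a (269.9 ± 13.2 TPM), Mki67 (22.3 ± 1.83 TPM, adjusted p = 0.0645) and Col1a1 (1289 ± 61.6 TPM) did not pass the test.

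In E76Q, chondrocyte genes (10 rose of 13, 10 adjusted over the list alone), BMP target genes (9 rose and 1 fell of 14, 10 and 1 adjusted over the list alone) and interferon-stimulated genes (25 rose of 42, 25 rose and 2 fell adjusted over the list alone) were higher. Their adjusted p was 1.36e-05, 7.07e-06 and 0.000119, and each had adjusted p = 0.987 with an estimated correlation. Col11a1 rose by 4.31, Bambi and Id4 by 3.16 and 4.16, and the interferon-induced genes Gbp3 and Ifit3 by 2.89 and 2.46. G1/S genes (34 fell of 36, 35 adjusted over the list alone), G2/M genes (26 fell of 38, 33 adjusted over the list alone) and ribosomal protein genes (50 fell of 78, 52 adjusted over the list alone) were lower, with adjusted p = 1.89e-08, 1.13e-05 and 3.12e-08 and adjusted p = 0.987 with an estimated correlation. Hells and Ndc80 fell by 1.85 and 1.62. As all E76Q libraries lay at the upper end of the axis and WT at the lower, and E71Q (-0.4 to 25.8) also lay above WT, what the cell cycle lists lost along the axis was not separated from the mutants. Amino acid response and ATF4 target genes (16 fell of 26, 16 fell and 1 rose adjusted over the list alone) and NF-kB and inflammatory genes (14 fell and 2 rose of 22, 15 and 2 adjusted over the list alone) were also lower, with adjusted p = 0.000967 and 0.00756 and adjusted p = 0.987 with an estimated correlation. Histone chaperones and H2B ubiquitin writers (13 fell and 3 rose of 25, 14 and 3 adjusted over the list alone) and heat shock genes (9 fell and 1 rose of 17, 9 and 1 adjusted over the list alone) fell as well. They had adjusted p = 0.00767 and 0.0307, and adjusted p = 0.987 with an estimated correlation. Psat1, an enzyme of serine synthesis, fell by 2.14 and Ccl2 by 3.38. TGF-beta target genes (9 rose and 3 fell of 23, 9 and 3 adjusted over the list alone) and collagen and matrix genes (18 rose and 5 fell of 35, 18 and 6 adjusted over the list alone) were higher with adjusted p = 0.0231 and 0.0311, and adjusted p = 0.987 with an estimated correlation, and had 0.0601 and 0.0647 after the rescaling. Tgfb2 rose by 3.87 and the matrix glycoprotein Thbs1 by 4.08.

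In E113K, where lysine replaces glutamate E113 of the acidic patch, more genes passed the test than in any other mutant. Mki67 (Entrez Gene 17345; chromosome 7, 135689784 to 135716450) was at 9.28 ± 0.785 against 40.7 ± 2.84 TPM in WT (SD, n = 3). Its log2 fold change was -2.02 ± 0.36 (SE; limma adjusted p = 0.000182). Rspo2 rose to 374 ± 9.56 TPM and Apod, the lipid carrier apolipoprotein D, to 119.8 ± 6.81 from 1.06 ± 0.391 TPM. Aspn, the matrix proteoglycan asporin, rose to 536 ± 66.5 from 16.2 ± 1.58 TPM, and Pgm5 to 125 ± 6.95 from 3.10 ± 0.595 TPM. Scrn1 and Hvcn1, a proton channel, rose by 5.11 and 4.91. The alpha globin gene Hba-a2 fell from 299.6 ± 3.62 to 1.36 ± 0.902 TPM, Ppef1 from 123 ± 4.98 to 0.98 ± 0.391 TPM and Lncenc1 by 6.25. Pparg rose 4.11-fold to 83.9 ± 6.40 TPM, Acta2 3.41-fold to 338 ± 5.77 TPM and Runx2, the regulator of bone cell differentiation, to 25.3 ± 2.11 TPM, and Cdkn1a fell to 169 ± 1.79 TPM. Sox9 (76 ± 2.52 TPM, adjusted p = 0.0744) and Col1a1 (1473 ± 20.7 TPM) did not pass the test.

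All 38 G2/M genes fell in E113K (38 adjusted over the list alone), with a median log2 fold change of -2.21, and 35 of 36 G1/S genes did (35 adjusted over the list alone), with a median of -1.68. The adjusted p was 2.41e-14 and 4.25e-16, and either list had adjusted p = 0.987 with an estimated correlation. Top2a, Aurkb and Hmmr fell by 2.76, 2.58 and 2.62, and Mcm5 by 2.49. Developmental transcription factors (27 rose and 1 fell of 37, 27 and 2 adjusted over the list alone), matrix metalloproteinases and protease inhibitors (14 rose of 19, 15 adjusted over the list alone), cholesterol synthesis genes (14 rose of 24, 15 adjusted over the list alone) and adipocyte genes (10 rose and 1 fell of 14, 10 and 1 adjusted over the list alone) were higher. In this order the adjusted p was 0.000675, 0.000222, 0.0134 and 0.0321, and each had adjusted p = 0.987 with an estimated correlation. Osr2 and Pax3 rose by 2.60 and 2.47, Adamts1 and Adamts5 by 3.85 and 2.78, Insig1 by 1.39, and the regulators of fat cell formation Zfp423 and Cebpd by 2.79 and 2.01. YAP/TEAD target genes (13 rose and 3 fell of 24, 13 and 3 adjusted over the list alone) were higher with adjusted p = 0.0293 and adjusted p = 0.987 with an estimated correlation. Within E71K, E71Q, E76K and E113Q the cholesterol list was higher toward the upper end of the axis, where all E113K libraries lay. Its rise in E113K was therefore not separated from the axis.

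Further lists were lower in E113K. They included amino acid response and ATF4 target genes (17 fell and 1 rose of 26, 17 and 1 adjusted over the list alone) and hypoxia and glycolysis genes (18 fell and 4 rose of 29, 18 and 4 adjusted over the list alone), with adjusted p = 3.16e-05 and 0.00419 and adjusted p = 0.987 with an estimated correlation. Ribosomal protein genes (16 fell and 1 rose of 78, 14 and 1 adjusted over the list alone) and replication-independent histone variants (7 fell of 11, 7 adjusted over the list alone) had 0.00576 and 0.00827. Either had adjusted p = 0.987 with an estimated correlation, and 36 ribosomal genes fell and 0 rose after the rescaling. Asns fell by 1.35, Pfkl by 1.34 and H2afz by 1.56, while the hypoxia-induced gene Adm rose by 3.23. Histone chaperones and H2B ubiquitin writers (11 fell and 4 rose of 25, 11 and 4 adjusted over the list alone), p53 target genes (11 fell and 3 rose of 27, 12 and 3 adjusted over the list alone) and heat shock genes (9 fell and 2 rose of 17, 10 and 2 adjusted over the list alone) had adjusted p = 0.0134, 0.0173 and 0.0197, and adjusted p = 0.987 with an estimated correlation. Asf1b fell by 2.58, and the p53 targets that fell the most, Gtse1 and Ckap2 (2.34 and 2.24), are also known to rise in mitosis. Epithelial and keratin markers (3 fell of 5, 3 adjusted over the list alone) and replication-dependent histone genes (14 fell and 7 rose of 54, 13 and 7 adjusted over the list alone) had adjusted p = 0.00956 and 0.0178, with adjusted p = 0.987 with an estimated correlation, and 0.0601 and 0.146 after the rescaling. Krt8 fell by 2.34.

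Tmtc4, among the genes that fell the most in E113K, stood at 0.0643 ± 0.0186 TPM against 70.2 ± 6.36 TPM in WT (SD, n = 3; chromosome 14, 122918971 to 122983285), and its neighbours were examined after this value was seen. Only tested protein-coding genes above about 5 TPM in at least 1 group, by its mean log2(TPM + 1) after the rescaling, were considered. Weaker genes were passed over. Of the 13 genes so kept from Rap2a (start 120478461) to Itgbl1 (end 123978865) on chromosome 14 of GRCm38, 8 were below 1 TPM in E113K. They were Dock9 (0.0628 ± 0.0152 against 9.57 ± 0.274 TPM in WT), Ubac2 (0.119 ± 0.0452 against 23.7 ± 1.24 TPM), Clybl, Zic2, Pcca, Ggact, Tmtc4 and Itgbl1 (0.678 ± 0.129 against 51.6 ± 0.932 TPM). Zic2 was low elsewhere too, at 2.59 TPM in WT, 0.021 TPM in E71K and 0 in E76Q. Tm9sf2, between Ubac2 and Clybl, was at 33.1 ± 1.62 against 85.6 ± 0.876 TPM. Rap2a, Ipo5, Farp1 and Stk24, before Dock9, were lower in E113K than in WT but not near 0. They were at 4.93, 17.6, 13.7 and 16.5 TPM in E113K against 24.1, 112, 23.1 and 47.7 TPM in WT. The ends of this stretch of 13 genes were drawn after values were seen. In E76K all 3 libraries were below all 3 WT libraries for 10 of the 13 genes, and Itgbl1 was at 4.10 ± 0.587 TPM. Of the 10313 protein-coding genes kept by the same rule over the genome 20.6% were so placed, where chance would give 5% in this direction and 10% in either.

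**Figure D4:**
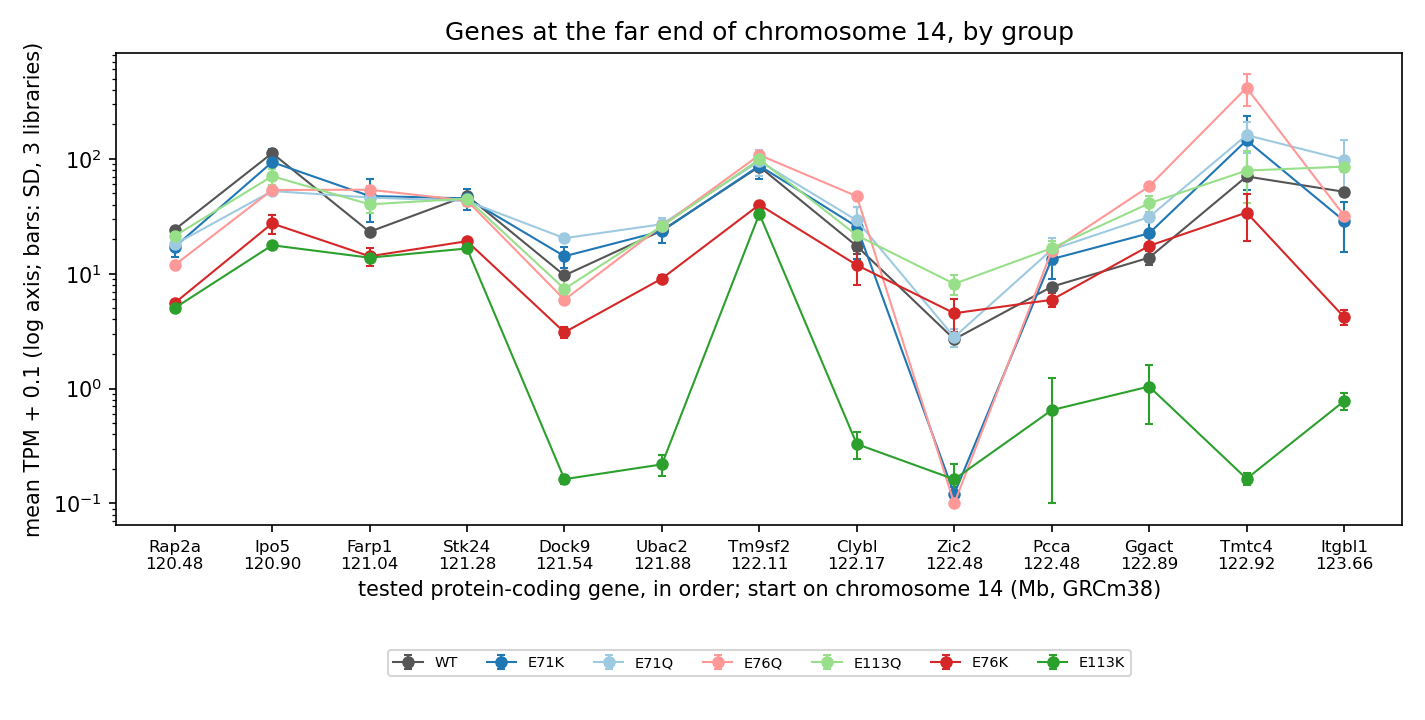
Mean TPM + 0.1 (log axis, bars SD, n = 3) of 13 neighbouring protein-coding genes at the far end of chromosome 14 in the 7 groups, in genome order from Rap2a to Itgbl1. In E113K 8 of the 13 lie below 1 TPM, and Tm9sf2, which lies between them, is at 33.1 TPM.

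In E113Q glutamine replaces glutamate E113, and Rspo2 had the largest rise of the named genes. It was at 237 ± 18.2 against 4.27 ± 0.394 TPM in WT (SD, n = 3). Its log2 fold change was 5.5 ± 0.46 (SE; limma adjusted p = 5.28e-08), and its relative Rspo3 was at 34.5 ± 5.87 against 0.175 ± 0.0856 TPM. Nov rose to 1003 ± 407 TPM, Ptx3 to 144 ± 44.6 TPM, Abi3bp to 54.3 ± 20.2 TPM and Hs6st2, a heparan sulfate sulfotransferase, to 68.9 ± 6.04 from 2.09 ± 0.244 TPM. G0s2, an inhibitor of fat breakdown, rose by 4.37 ± 0.51, with 59.07 TPM in replicate 3 against 14.19 and 11.44 TPM in its mates. Gpnmb fell from 78.5 ± 6 to 0.389 ± 0.153 TPM, Ppef1 to 1.23 ± 0.437 TPM and Efemp1 to 5.06 ± 1.79 TPM, and Ptprtos, at 60.4 ± 3.41 TPM in WT, was listed at 0 in all E113Q libraries. Pparg (36.4 ± 7.25 TPM), Sox9 (118 ± 25.3 TPM), Acta2 (175 ± 4.87 TPM) and Col1a1 (1858 ± 168 TPM) rose. Runx2 (16.7 ± 1.31 TPM), Cdkn1a (249 ± 7.75 TPM) and Mki67 (35.9 ± 19.9 TPM) did not pass the test.

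In E113Q, interferon-stimulated genes (20 rose and 3 fell of 42, 23 and 3 adjusted over the list alone) and BMP target genes (7 rose of 14, 7 adjusted over the list alone) were higher, with adjusted p = 0.00418 and 0.0154 and adjusted p = 0.987 with an estimated correlation. The interferon list stood at 1.07 and 1.12 in replicates 1 and 2 and at -0.02 in replicate 3, and the sensor gene Ifih1 rose by 3.03. G1/S genes (16 fell of 36, 18 adjusted over the list alone), ribosomal protein genes (8 fell of 78, 4 adjusted over the list alone), NF-kB and inflammatory genes (9 fell and 1 rose of 22, 9 and 1 adjusted over the list alone) and hypoxia and glycolysis genes (10 fell and 2 rose of 29, 12 and 2 adjusted over the list alone) were lower. The adjusted p was 1.72e-06, 0.000918, 0.00754 and 0.00754, and each had adjusted p = 0.987 with an estimated correlation. Ccl7 fell by 3.49 and Vegfa by 1.15. Cholesterol synthesis genes (4 fell of 24, 4 adjusted over the list alone), histone chaperones and H2B ubiquitin writers (8 fell and 1 rose of 25, 9 and 1 adjusted over the list alone) and G2/M genes (2 fell of 38, 0 adjusted over the list alone) had adjusted p = 0.0109, 0.0272 and 0.0198, and adjusted p = 0.987 with an estimated correlation. The cholesterol list stood at -0.55 and -0.53 in replicates 1 and 2 and at 0.15 in replicate 3, and 20 of its 24 genes fell without the libraries that lay apart and 8 after the rescaling. Ribosomal genes that fell then numbered 5 and 18, and 35 interferon-stimulated genes rose without those libraries. The G2/M list stood at -1.62 in replicate 3 and at 0.25 and 0.20 in its mates, and had an adjusted p of 0.312 without the libraries that lay apart and 0.0864 after the rescaling. Of all 12192 tested genes 1551 fell in E113Q, a larger share than of the ribosomal or the G2/M genes.

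Over the 6 mutants, 66 of 198 list tests passed camera with the preset correlation and 0 with an estimated correlation, where 0.987 was the lowest adjusted p, so each list's count of members rests on the test of single genes. These counts are to be read beside those of all 12192 tested genes. Against WT 1523 rose and 1727 fell in E71K, 2524 and 2864 in E71Q, and 2865 and 1179 in E76K. In E76Q 2677 rose and 2726 fell, in E113K 3692 and 2523, and in E113Q 2183 and 1551. With an estimated correlation 5 of the 198 camera tests had an unadjusted p below 0.05, among them NF-kB and inflammatory genes (0.0158) and BMP target genes (0.0163) in E71K. That is a smaller share than the 0.05 that chance alone would give, so these p-values lend the lists no weight. Ribosomal protein genes were the 1 list past the threshold in all 6 mutants. Their median log2 fold change ran from -0.46 in E71Q to -0.12 in E113K, with -0.13 in E113Q. In E113K and E113Q 16 and 8 of the 78 fell, no larger a share than among all tested genes. For 7 lists no mutant passed, the lowest adjusted p being 0.057. Among these were osteoblast genes (6 rose and 2 fell of 11 in E113K, 6 and 2 adjusted over the list alone), skeletal muscle genes (4 rose and 3 fell of 10 in E71Q, 5 and 3), and Wnt target genes (4 rose and 3 fell of 8 in E76Q, 4 and 3). The others were chromatin remodeller subunits (11 fell and 3 rose of 37 in E71Q, 11 and 3), imprinted genes (7 rose and 1 fell of 12 in E76Q, 7 and 1), unfolded protein response genes (5 rose and 3 fell of 22 in E76K, 6 and 3) and neural markers (6 rose and 2 fell of 9 in E71Q, 6 and 3). After the rescaling chromatin remodeller subunits passed in E71Q (15 fell and 5 rose, adjusted p = 0.0431, and adjusted p = 0.987 with an estimated correlation as deposited). The median, the mean and the camera direction differed in sign in 37 of the 132 list tests that did not pass and in 0 of the 66 that did. Markers of macrophages and leukocytes, of endothelium and of germline and pluripotent cells had 4, 3 and 3 members with a mean of at least 1 TPM, and the mitochondrially encoded genes 0, too few to test.

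**Figure D5:**
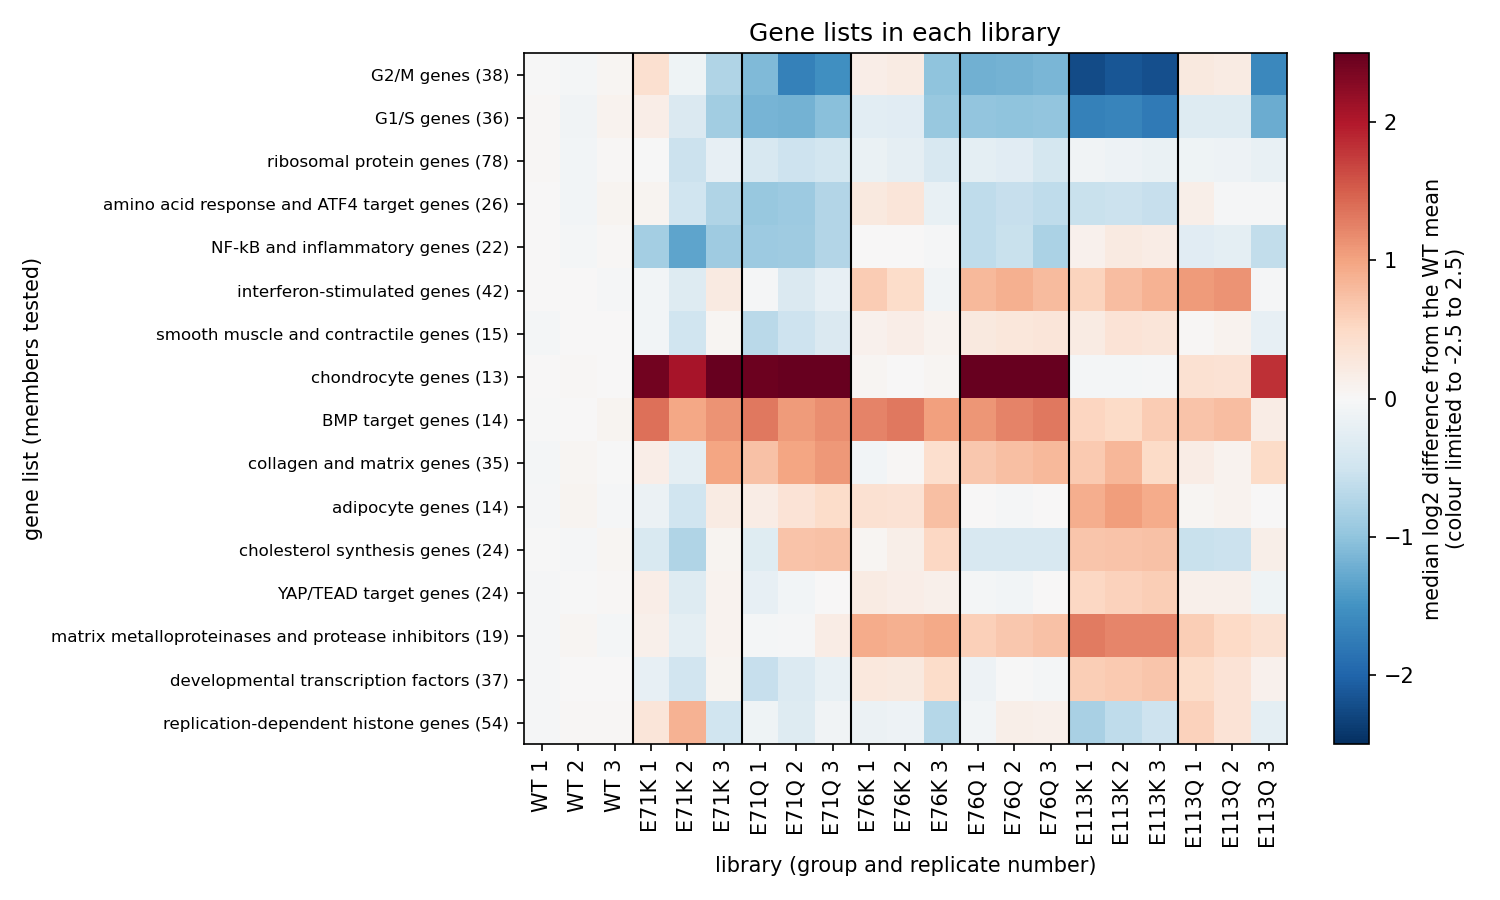
Median log2 difference from WT (colour, from -2.5 to 2.5) of the members of 16 gene lists in each of the 21 libraries. The G2/M row is lowest in the 3 E113K libraries (-2.23 to -2.13) and the chondrocyte row is above 2 in all E71K, E71Q and E76Q libraries.

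Lysine and glutamine at the same residue were then compared directly, and gene lists were tested between mutants as an addition made after the data were seen. At E71, 3060 genes passed (1565 higher in E71K, 1495 lower). Ly6e, an interferon-induced membrane protein, was at 1.31 ± 0.763 TPM in E71K and 123 ± 22.2 TPM in E71Q (SD, n = 3). The log2 difference was -5.78 ± 0.24 (SE; limma adjusted p = 2.87e-11). Ptgis, prostacyclin synthase, was at 0.393 ± 0.196 and 50.4 ± 13.5 TPM, and Eln at 2.95 ± 4.22 and 159 ± 135 TPM. Rap1gap, Ldb2 and Smoc2 were higher in E71K by 4.96, 4.60 and 4.59. Of the G2/M genes 29 of 38 were higher in E71K (37 adjusted over the list alone; adjusted p = 5.67e-10, and adjusted p = 0.864 with an estimated correlation). Of the cholesterol synthesis genes 14 of 24 were lower (16 adjusted over the list alone; adjusted p = 5.71e-07, and adjusted p = 0.864 with an estimated correlation). The G2/M list ran from -0.76 to 0.41 in the E71K libraries and from -1.68 to -1.11 in those of E71Q. The cholesterol list overlapped, at -0.39, -0.76 and 0.07 in E71K and -0.30, 0.71 and 0.74 in E71Q. The count was 6541 without the libraries that lay apart and 346 in a fit of these 6 libraries alone.

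At E76, 3890 genes passed between E76K and E76Q (2858 higher in E76K, 1032 lower), and 73.5% of them were higher in E76K against 49.5% after the rescaling. Efemp1 was at 180 ± 34.7 TPM in E76K and 0.742 ± 0.268 TPM in E76Q (SD, n = 3). The log2 difference was 6.69 ± 0.29 (SE; limma adjusted p = 7.83e-12). The surface glycoprotein Thy1 was at 106 ± 4.23 and 0.472 ± 0.140 TPM, the retinoic acid-binding protein Crabp2 at 97.2 ± 15.4 and 0.573 ± 0.0882 TPM, and Arl6ip1 at 139 ± 27.5 and 1.37 ± 0.222 TPM. The cartilage collagen Col9a1 was at 1.23 ± 0.342 TPM in E76K and 253 ± 11.7 TPM in E76Q, and Sorbs2 at 2.34 ± 0.879 and 142 ± 11.4 TPM. Chondrocyte genes were lower in E76K (9 of 13, 11 adjusted over the list alone; adjusted p = 3.61e-10, and adjusted p = 0.864 with an estimated correlation). So were interferon-stimulated genes (10 lower and 1 higher of 42, 10 and 0 adjusted over the list alone; adjusted p = 1.37e-06, and adjusted p = 0.884 with an estimated correlation). The interferon list stood at 0.63 and 0.45 in E76K replicates 1 and 2 and at -0.09 in replicate 3, against 0.79 to 0.89 in E76Q. Without the libraries that lay apart 26 of its 42 genes rose in E76K against WT, where 10 did with them.

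At E113, 3408 genes passed between E113K and E113Q (1786 higher in E113K, 1622 lower; 52.4% higher, but 46.4% after the rescaling). All 38 G2/M genes were lower in E113K (38 adjusted over the list alone; adjusted p = 3.33e-16, and adjusted p = 0.864 with an estimated correlation). In turn 22 of 24 cholesterol synthesis genes were higher (22 adjusted over the list alone; adjusted p = 3.22e-09, and adjusted p = 0.864 with an estimated correlation). Itgbl1 was at 0.678 ± 0.129 TPM in E113K and 85.5 ± 9.12 TPM in E113Q (SD, n = 3). The log2 difference was -5.69 ± 0.31 (SE; limma adjusted p = 8.39e-10). Tmtc4 was at 0.0643 ± 0.0186 and 79.0 ± 38.1 TPM, and Hvcn1 at 37.5 ± 5.08 and 0.471 ± 0.159 TPM. The remaining genes with the largest changes were short RNA loci such as Snora41 and Mir215, whose TPM can rest on very few reads. The G2/M list was at -1.62 in E113Q replicate 3, nearest to the E113K libraries. The cholesterol list was at 0.15 in that library, against -0.55 and -0.53 in its mates and 0.70 to 0.73 in E113K. All E113K libraries lay at the upper end of the axis, so the difference of either list was not separated from the axis.

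The K minus Q difference itself differed between residues, by a test of the interaction. It passed for 2644 genes between E76 and E71 (1876 with a higher and 768 with a lower difference at E76), for 3985 between E113 and E71 (2025 and 1960) and for 3591 between E113 and E76 (1176 and 2415). The share that was higher was 71% between E76 and E71, 50.8% between E113 and E71 and 32.7% between E113 and E76, against 50.8%, 47.7% and 47.6% after the rescaling.

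Among the lysine mutants, E76K and E71K differed in 3578 genes (2645 higher in E76K, 933 lower; 73.9% higher, and 52.4% after the rescaling). Grem1 was at 143 ± 49.3 TPM in E76K and 0.0528 ± 0.0478 TPM in E71K (SD, n = 3). The log2 difference was 7.03 ± 0.39 (SE; limma adjusted p = 2.51e-10). Thy1, Arl6ip1 and Efemp1 were higher in E76K by 6.63, 6.17 and 6.08. Krt14 was at 5.45 ± 4.37 TPM in E76K and 294 ± 203 TPM in E71K, and Sema3c at 0.133 ± 0.0675 and 44.2 ± 20.2 TPM. Of the chondrocyte genes 9 of 13 were lower in E76K (9 adjusted over the list alone; adjusted p = 3.1e-09, and adjusted p = 0.864 with an estimated correlation). Of the NF-kB and inflammatory genes 12 of 22 were higher (15 adjusted over the list alone; adjusted p = 0.000179, and adjusted p = 0.864 with an estimated correlation). The count was 5421 without E71K replicate 3, 5971 without the libraries that lay apart and 1070 in a fit of these 6 libraries alone.

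E113K and E71K differed in 5764 genes (3449 higher in E113K, 2315 lower; 59.8% higher, and 48.5% after the rescaling). Anpep, a membrane aminopeptidase, was at 185 ± 8.94 TPM in E113K and 0.108 ± 0.156 TPM in E71K (SD, n = 3). The log2 difference was 7.40 ± 0.19 (SE; limma adjusted p = 3.02e-14). Aspn was at 536 ± 66.5 and 6.44 ± 8.06 TPM, and the deacetylase gene Hdac11 at 106 ± 9.62 and 0.0238 ± 0.0411 TPM. Krt14 and Col9a1 were lower in E113K, with log2 fold changes of -7.81 and -6.08. All 38 G2/M genes were lower in E113K (38 adjusted over the list alone) and 28 of 37 developmental transcription factors higher, with 1 lower (29 and 1 adjusted over the list alone). Their adjusted p was 4.75e-14 and 2.15e-06, and either had adjusted p = 0.864 with an estimated correlation. Between E113K and E76K, 3994 genes passed (1538 higher in E113K, 2456 lower; 38.5% higher, but 46.5% after the rescaling). Hdac11 was at 0.0487 ± 0.0514 TPM in E76K, Cdo1, a cysteine-degrading enzyme, at 114 ± 7.74 TPM in E113K and 0.925 ± 0.609 TPM in E76K, Lyz2, lysozyme, at 0.385 ± 0.158 and 74.6 ± 25.1 TPM, and the X-linked homeobox gene Rhox5 at 11.3 ± 0.565 and 577 ± 107 TPM. All 38 G2/M genes were lower in E113K (38 adjusted over the list alone; adjusted p = 1.78e-12, and adjusted p = 0.864 with an estimated correlation). Of the immediate early genes 14 of 26 were higher (16 adjusted over the list alone; adjusted p = 7.43e-07, and adjusted p = 0.864 with an estimated correlation).

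Among the glutamine mutants, E76Q and E71Q differed in 2406 genes (1181 higher in E76Q, 1225 lower; 49.1% higher, but 52.3% after the rescaling). Il1rn was at 123 ± 2.64 TPM in E76Q and 0.443 ± 0.245 TPM in E71Q (SD, n = 3). The log2 difference was 6.44 ± 0.19 (SE; limma adjusted p = 2.66e-13). Smoc2 was at 99.2 ± 5.47 and 0.519 ± 0.1 TPM, and the endothelial factor Esm1 at 46.4 ± 0.727 TPM in E76Q and listed at 0 in all E71Q libraries. Tcf7, a transcription factor of the Wnt pathway, was at 0.0203 ± 0.0352 TPM in E76Q and 220.5 ± 54.8 TPM in E71Q, and Slurp1 at 3.06 ± 1.25 and 638 ± 548 TPM. Interferon-stimulated genes were higher in E76Q (30 of 42, 33 adjusted over the list alone; adjusted p = 3.68e-12, and adjusted p = 0.864 with an estimated correlation). Smooth muscle and contractile genes were higher too (9 of 15, 12 adjusted over the list alone; adjusted p = 1.93e-08, and adjusted p = 0.864 with an estimated correlation). E113Q and E71Q differed in 2856 genes (1779 higher in E113Q, 1077 lower; 62.3% higher, and 50.5% after the rescaling). Nov was at 1003 ± 407 TPM in E113Q and 11.2 ± 2.01 TPM in E71Q, Hs6st2 at 68.9 ± 6.04 and 0.33 ± 0.0616 TPM, and Bglap2 at 17.2 ± 24.7 and 663 ± 491 TPM. Of the amino acid response and ATF4 target genes 21 of 26 were higher in E113Q (24 adjusted over the list alone; adjusted p = 1.99e-11, and adjusted p = 0.864 with an estimated correlation). E113Q and E76Q differed in 2692 genes (1699 higher in E113Q, 993 lower; 63.1% higher, and 48.2% after the rescaling). Thy1 was at 94.2 ± 35.0 TPM in E113Q and 0.472 ± 0.140 TPM in E76Q, Anpep at 58.1 ± 12.4 and 0.256 ± 0.0186 TPM, Col9a1 at 1.85 ± 1.79 and 253 ± 11.7 TPM, and Slpi, a secreted protease inhibitor, at 22.0 ± 3.46 and 1068 ± 124 TPM. BMP target genes were lower in E113Q (9 lower and 1 higher of 14, 10 and 1 adjusted over the list alone; adjusted p = 0.000162, and adjusted p = 0.864 with an estimated correlation). The list stood at 0.71, 0.77 and 0.19 in the E113Q libraries, replicate 3 being the lowest, and at 1.10 to 1.32 in E76Q.

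Fold changes against WT were correlated across genes for each of the 15 pairs of mutants, genes not being independent replicates. Pearson's r was highest for E71Q with E76Q (0.746), E71K with E71Q (0.745) and E113K with E113Q (0.727) and lowest for E71K with E113K (0.456). Groups simulated without any change against the same 3 WT libraries gave r = 0.5, where shared noise was the only signal. With many changed genes the shared noise weighs less, so 0.5 is not a floor for these mutants. E71K with E113K lay below it in r but had a covariance of 0.3625. The covariance was 0.668 for E71Q with E76Q and 0.352 for E71K with E76K, the highest and lowest of the 15, against 0.0524 in the simulation. The simulation held only noise. On the axis of differences within groups WT lay at -30.6 to -28.2 and every mutant library above it, the lowest at -24.8. Such an offset of WT enters all 15 covariances and is absent from the simulated value. E71Q and E76Q shared 1576 genes that rose and 1914 that fell, where independent lists would share 554 and 640, and 144 moved in opposite directions where 1193 would. In 20 simulations of unchanged groups against shared controls, E71K and E71Q shared at most 0 called genes in the same direction, and other pairs were not counted. With 3 WT libraries the controls could not be divided with at least 2 on each side, so part of the excess may come from the shared controls.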

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

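The comparisons and the counts of other splits were planned before the data were examined, and the 4 tests below of Mir6236, of dividing cells, of strongly parted coding genes and of true libraries of other groups were chosen only after the result was seen.

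The difference between lysine and glutamine differed between residues by a test of the interaction, which is what brought these results here. It passed for 2644 genes between E76 and E71, 3985 between E113 and E71 and 3591 between E113 and E76. Of 100 splits of the 12 libraries only the real 1 gave as many genes in each of the 3 (highest others 1822, 3418 and 1339). These splits exchange libraries among all the groups in the interaction, which differ strongly. They argue against libraries without any group difference. They cannot test whether lysine minus glutamine is equal at the residues, which rests on the limma test. For any difference among the 7 groups again only the real 1 of 100 splits gave as many, with 9404 genes against 842. For the number of gene lists 22 of 100 splits of the 21 libraries gave 66 or more, with 81 as the highest other, so chance cannot be excluded for the list count.

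For groups of 3 against 3 there are 10 splits, too few for a share under 0.05. The real split, 1 of the 10, gave the most genes in 14 of the 15 comparisons. Every other split put libraries of both groups on both sides, so a difference between the groups added to the spread within the sides. Low counts of other splits follow in part from this mixing and are not a rate of false calls. The real and highest other counts were 3250 and 1 for E71K, 5388 and 0 for E71Q, 4044 and 1 for E76K, 5403 and 0 for E76Q, 6215 and 1 for E113K and 3734 and 1 for E113Q against WT. They were 3890 and 1 for E76K with E76Q, 3408 and 2 for E113K with E113Q, 3578 and 34 for E76K with E71K, 5764 and 2 for E113K with E71K, 3994 and 2 for E113K with E76K, 2406 and 0 for E76Q with E71Q, 2856 and 417 for E113Q with E71Q and 2692 and 0 for E113Q with E76Q. For E71K with E71Q 2 of the 10 splits gave as many as the real 3060. The other, with 5021 genes, set E71K replicates 1 and 2 and E71Q replicate 1 against E71K replicate 3 and E71Q replicates 2 and 3, which follows the axis of differences within groups and points to a structure of the samples.

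In each of E71K, E71Q, E76K and E113Q 1 library lay apart from its mates along this axis. The share of TPM taken by Mir6236 went with the axis in 2 of the 4 groups, which argues against it as the whole cause. A mislabelled library was tested first with all genes that part a library's mates from the closest other group by a log2 gap of at least 2, with a bound of 50%. E113Q replicate 3 fell below it (46.5% nearer its mates) and E71K replicate 3 was little above it (55.1%), while E71Q replicate 1 and E76K replicate 3 had 75.3% and 79.7%. That bound was set without a control: true E113K libraries, left out in turn and placed by the same genes, were nearer the E113Q mates for only 5.5% to 8.2% of them, against 44.9% to 50.2% for E113Q replicate 3. Over the 4 libraries and each of the 6 other groups the lowest margin over a true library was 25.8 percentage points (E71K replicate 3 with E71Q, and E71Q replicate 1 with E71K). Of protein-coding genes with a log2 gap of at least 4 the lowest share was 77.8% (14 of 18, E71K replicate 3), and all 8 placed E113Q replicate 3 with its mates. These values argue against a library of another of the 7 groups under a wrong label, and a sample from outside the series has no libraries here to be set against. In 4 of the 4 groups every library toward the upper end had a lower G2/M value than every mate toward the lower end, so fewer dividing cells may be part of what the axis measures. The axis was made from all tested genes, and only the G2/M list was put to this test. The cholesterol synthesis list parted the same libraries, with higher values toward the upper end. It stood at 0.07 against -0.39 and -0.76 in E71K, and at 0.71 and 0.74 against -0.30 in E71Q. In E76K it stood at 0.52 against 0.05 and 0.14, and in E113Q at 0.15 against -0.55 and -0.53. The axis is thus not particular to dividing cells. No label gives a batch, harvest day or cell density, so what made these libraries differ stays open.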

How the results depend on the processing

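Leaving out Mir6236, the libraries set apart, and single libraries for the interactions and the F test were chosen after the data were seen. Of 473 alternatives for 35 counts and similarities 409 stayed within 1.5 times or the spread and 64 moved, and of 15992 alternatives for 897 values of named genes 15595 kept their direction and side of the threshold, 369 ended a call, 16 made one and 12 reversed a direction.

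Requiring a 2-fold change lowered the counts by construction, to 1201, 1908, 1261, 1894, 2200 and 1215 for E71K, E71Q, E76K, E76Q, E113K and E113Q against WT, 819, 1194 and 1014 for lysine against glutamine at E71, E76 and E113, 1172, 2042 and 1343 for E76K with E71K, E113K with E71K and E113K with E76K, 817, 983 and 940 for E76Q with E71Q, E113Q with E71Q and E113Q with E76Q, and 1394, 2073 and 1930 for the interactions of E76 with E71, E113 with E71 and E113 with E76. The median-ratio rescaling gave 5135 for E71K with WT, 5263 for E71K with E71Q, 5302 for E113K with E113Q, 4385 for E76Q with E71Q, 4576 for E113Q with E71Q, 4415 for E113Q with E76Q, 4341 for E76 with E71 and 5403 for E113 with E76. Quantile normalization gave 5076, 5147, 5295, 4276, 4505, 4468, 4364 and 5522 in the same order. Leaving out Mir6236 gave 5238 for E71K with WT, 4973 for E71K with E71Q, 4115 for E76Q with E71Q, 4377 for E113Q with E71Q, 4241 for E113Q with E76Q and 4082 for E76 with E71. Leaving out the libraries set apart gave 4939 for E71K with WT, 6541 for E71K with E71Q, 6054 for E76K with E76Q, 5486 for E113K with E113Q, 5971 for E76K with E71K, 6114 for E113K with E76K, 4370 for E76Q with E71Q, 5376 for E113Q with E71Q, 5365 for E113Q with E76Q, and 5557, 7015 and 6100 for the 3 interactions. Fits of only the libraries compared gave 1442 for E71K with WT, 6136 for E76K with WT, 8276 for E76Q with WT, 346 for E71K with E71Q, 1070 for E76K with E71K, 3050 for E113K with E71K and 1323 for E113Q with E71Q. Camera with an estimated correlation passed 0 lists. Fits of all libraries take a single spread for each gene from every group, though on the axis E71K spanned 41.6 and E76Q 0.6. P-values of the more spread groups thus borrow from the tighter groups, and the order of mutants by count can depend on this. Beyond the size threshold the cause was not tested.

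Leaving out each library in turn gave 2514 to 4359 genes for E71K, 4293 to 5686 for E71Q, 2828 to 3387 for E76K, 4312 to 4556 for E76Q, 5227 to 5503 for E113K and 2752 to 3239 for E113Q against WT. It gave 1815 to 4713 for E71K with E71Q, 2812 to 3697 for E76K with E76Q, 2386 to 3315 for E113K with E113Q, 2751 to 5421 for E76K with E71K, 4828 to 6990 for E113K with E71K, 3002 to 3918 for E113K with E76K, 1727 to 2354 for E76Q with E71Q, 1961 to 3724 for E113Q with E71Q and 1911 to 3340 for E113Q with E76Q. The ranges were 2115 to 3850, 3264 to 5490 and 2857 to 4011 for the 3 interactions and 8670 to 10360 for the F test. The lists were run without each WT library only (67 to 71). Counts that moved by over 1.5 times were E71K with E71Q without E71K replicate 1 (1901), without E71K replicate 3 (4713) and without E71Q replicate 2 (1815), and E76K with E71K without E71K replicate 3 (5421).

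The reversed values were of genes that had not passed the test. Left out in turn, libraries gave -0.69 to 0.068 for Runx2 in E71K vs WT (reversed without E71K replicate 2), -0.092 to 0.428 for Mki67 in E71K vs WT (reversed without E71K replicate 1) and -0.273 to 0.161 for Mki67 in E76K vs WT (reversed without E76K replicate 3). They gave -0.702 to 0.214 for Mki67 in E113Q vs WT (reversed without E113Q replicate 3), -0.039 to 0.03 for Cdkn1a in E76Q vs WT (reversed without E76Q replicate 3) and -0.008 to 0.057 for Col1a1 in E76Q vs WT. The last was reversed without WT replicate 1 (-0.008), E76Q replicate 2 (-0.003) or E76Q replicate 3 (-0.005). Without the libraries set apart Mki67 was at 0.161 in E76K and 0.214 in E113Q. Cdkn1a in E76Q was at 0.032 with quantile normalization and 0.088 with Mir6236 left out. The cause was not tested. Replicate number as a block moved no count by 1.5 times (E71K with WT 3395, lists 71), and the 63 pairs of libraries with the same number had a median r of -0.001 after group means were removed, with 13 pairs above 0.1 and the highest at 0.42. Whether the numbers pair some of the samples stays open, and they were not used as pairs. Comparing only libraries on 1 side of the axis, and a term for the side, were tried and dropped, because they pick libraries by their expression and WT, E76Q and E113K lie on 1 side only. Depth is unknown, which limits what values near 0 can show.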

Other observations

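The tests of G2/M genes and of chromosome 14 were chosen only after the result was seen, and the test of Xist was written before it.

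The fall of the G2/M list in E113K was not an effect of the share of TPM taken by Mir6236. That share was 2.19% to 2.91% in E113K and 3.77% to 7.26% in WT, and a lower share raises the values of other genes. The list's median log2 fold change was -2.34 after the median-ratio rescaling, which with these shares could not have ended the fall. On this list, as deposited, the 3 E113K libraries stood at -2.23 to -2.13 and the lowest other library, of E71Q, at -1.68. A slower cycle caused by the mutant histone cannot be told apart from whatever set libraries apart in other groups, because all 3 E113K libraries lie at the same end of the axis.

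The genes near 0 at the far end of chromosome 14 in E113K included a run of 4 neighbours, Pcca to Itgbl1, with a mean log2(TPM + 1) after the rescaling below 1 in E113K and a median above 2 over the other groups, and 0 of 1000 shuffles of the gene order gave a run as long (longest 3), which argues against chance neighbours. In E76K the window's median log2 fold change was -1.26, and 12 of 10073 windows of 13 genes were as low. The windows were slid by 1 gene and overlap, and the 12 include this window, so their share is not a p-value. The window was drawn after values were seen. It begins with Rap2a, Ipo5, Farp1 and Stk24, which were not near 0 in E113K but had log2 fold changes of -2.1, -2.18, -0.84 and -1.43 in E76K. Its rank in E76K therefore describes the window and does not test it. A single deleted segment from Dock9 to Itgbl1 on every copy is argued against by Tm9sf2, which lies inside it at 33.1 TPM. Silencing, or several losses arising in the cell line, may underlie the pattern, and neither was tested.

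Xist, the RNA that silences an X chromosome, was at 12.2 ± 1.88 TPM in WT, 21.4 TPM in E113K, 21.1 TPM in E113Q and 10.4 TPM in E76Q, but at 0.911 TPM in E71Q, 0.027 TPM in E76K and 0.00982 TPM in E71K. It was chosen after its values were seen to differ. A higher Xist level was tested for a lower level of 416 X-linked genes relative to 11764 autosomal genes over the 7 groups. Pearson's r was 0.176 (exact permutation p = 0.695) and Spearman's rho 0.214 (exact permutation p = 0.662), and r was 0.749 without E71K and E76K, so no lower level of X-linked genes went with Xist.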
